A study of Homo sapiens with 9 samples.

How the data were processed

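The samples were 9 polyadenylated RNA libraries of Nalm-6, a human precursor B cell leukaemia line, in a version carrying SF3B1 K700E. SF3B1 is a core subunit of the SF3b complex, which recognises the branch point near the 3' end of introns. Per the sample titles, 3 libraries came from cells given 13 nM H3B-8800 for 6 h and 3 from cells given 15 nM E7107 for 6 h. The titles of the other 3 named no compound, dose or time, and these are called untreated here. Whether they were given a vehicle was not said in the titles. Nothing in the labels said that the 3 libraries of a group came from separate cultures, so p-values measured the spread between these libraries, which may be technical.

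The reads were aligned with STAR to hg19, per the submitters' processing notes. Its version, the counting of junction reads and any filter were not given in the sources used here. Each deposited table held 1310380 rows with a genomic interval, a strand, the word start or end, and a percent between 0 and 100. The rows fell into 909370 rows of splice junctions and 401010 rows only 2 bases wide, placed at a junction's boundary. Over the 478924 splice sites (the lower coordinate of start rows, the higher one of end rows), the deposited percent values of a site summed to 100 within 0.02 or were all 0. A row was therefore read as the share of the site's reads that used the junction, and a 2-base row as the share that ran unspliced across the boundary. That reading rested on the structure of the tables. A site at 0 in all rows was treated as having no value in that library. Read depth was unknown, so no counting interval or detection floor was given. The share of sites without a value was 32.3% to 33.7% in untreated libraries, 37.0% to 37.3% with H3B-8800 and 44.2% to 45.6% with E7107, and 203962 sites had a value in all 9 libraries.

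The intervals were numbered from 0 in the tables; positions given here are in hg19, numbered from 1. The tables did not pair their intervals with gene names, and the gene annotation at hand was for another genome build, with no conversion between builds made. Features were therefore described by position, length and class, no gene name was assigned, and the 23 gene lists written before the data were examined were not tested. Gene expression was not analysed here, since the values were percentages within a splice site and not counts. GC content of introns was not computed because no hg19 sequence was used.

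Percent unspliced of an intron was the mean of its 2 boundary percentages. Introns were junctions of at least 21 nt that held at least 50% of the spliced reads at both of their sites (mean over the 9 libraries), with values at both boundaries in all libraries, which left 79544. A further 13347 such junctions had values in all libraries but no 2-base row at 1 or both sites and were not given a percent unspliced. No tested intron was at 0% unspliced in all 9 libraries, so 2-base rows may be listed only where some library had unspliced reads. If so, some of the 13347 may be fully spliced, and introns could enter the tested set through treated libraries alone. Means and shares over the tested introns may then be too high. Junction usage was the junction's share of the spliced reads at its 5' splice site, for sites with at least 2 junctions, values in all 9 libraries and a mean usage of 1% to 99%, which left 135717 junctions at 52290 sites. At a site with 2 junctions, both rows mirror each other and are counted separately. The main junction of a 5' site was the most used one over the 9 libraries. A junction was classed as exon-skipping when it passed over the main 3' site and over a 5' site downstream of that. A second junction, from that 5' site to the same 3' site, had to hold at least 20% of the spliced reads at 1 or both of its sites (mean over the 9 libraries). Pairs of 3' sites shared a 5' site and had at least 5% mean usage each over the 9 libraries. A near pair lay 10 to 30 nt apart and a far pair 31 to 100 nt apart. Introns of 1 strand separated by exons of at most 500 nt were linked into chains, as a stand-in for transcripts.

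Percentages were tested with limma 3.58.1 in R 4.3.3, on log2((percent + 1)/(101 - percent)), with all 9 libraries in 1 fit, the group as the only term and a trend in the spread. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 and a change in mean percent of at least 10 percentage points. Count-based tests had been planned; limma on percentages, the fallback planned for junctions, replaced them because the tables hold no counts. For retention the plan had been to run no test without counts, so this part departs from it. On simulated data for H3B-8800 against untreated, with 200 features given known changes, a change of 2 in log2 odds was recovered in 17% of introns (79544 tested) and 2% of junctions (135717 tested), and a change of 4 in 86% and 16%. In that simulation most introns with the smaller change, and most junctions with either change, were thus missed. Only 200 features were changed there, so far fewer passed the adjusted p than in the data (17287 introns and 16944 junctions). The cutoff on the unadjusted p was therefore stricter there, and these shares do not give the recovery in the data. Of the simulated features past the adjusted p, 8.85% (10 introns) and 18.2% (4 junctions) were unchanged ones. They come from a single draw and few features, and do not give the false share among the calls in the data.

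Per-library values were compared with a two-sided exact permutation test, which cannot go below 0.1 with 3 libraries against 3. Intron lengths were compared with a two-sided permutation test of 100000 resamples across introns, which are not independent replicates. Features named in the text were those with the largest rise and the largest fall per comparison and kind, among called features whose groups did not overlap. Ties were broken by the smaller adjusted p and then by row label. The rule fixed beforehand asked for more features, for gene names and for a read minimum, none of which could be applied. Ranking by size of change without a read minimum can favour sites with few reads. Where a named feature had no spread in any group, its p-value rested on the spread of other features. Alternatives chosen after the data were seen were an adjusted p under 0.01 for the counts (planned for the overlap), exon-skipping junctions defined in untreated libraries, pseudocounts of 0.1 and 5, no trend in the spread, a mean of 5% to 95%, the deposited denominator for junction usage and a length background matched on the untreated percent unspliced. The groups, the comparisons, the thresholds for calls and the other alternatives had been fixed before. The classes of junctions, the pairs of 3' sites, the share of reads that went to other junctions, the chains and the bins of length were also chosen after the data were seen.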

Results

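The data described splicing in Nalm-6 cells with SF3B1 K700E, untreated or treated for 6 h with a splicing modulator, with 3 libraries per group. The doses differed, 13 nM for H3B-8800 and 15 nM for E7107, so the compounds are set side by side and not at a matched dose. Percent unspliced was available for 79544 introns and usage for 135717 junctions. Read depth was unknown. Over the 2-base rows with values in all libraries, Pearson's r across sites was 0.941 to 0.943 between untreated libraries, 0.922 to 0.925 with H3B-8800 and 0.857 to 0.864 with E7107. Between groups it was 0.844 to 0.857 for untreated and H3B-8800 libraries, 0.569 to 0.580 for untreated and E7107 and 0.637 to 0.645 for H3B-8800 and E7107. E7107 libraries differed more from each other (mean absolute difference 8.19 to 8.35 percentage points) than untreated from H3B-8800 libraries (5.24 to 5.66). Sites are not independent replicates.

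Both treatments left more RNA unspliced, and E7107 did so to a larger extent. The mean percent unspliced over all tested introns was 3.57% ± 0.140 (SD, n = 3) in untreated cells, 7.48% ± 0.208 (SD, n = 3) with H3B-8800 and 19.2% ± 0.235 (SD, n = 3) with E7107. Some introns may be in the set only through unspliced reads in treated libraries, so these means describe the tested introns. The share of spliced reads at an intron's 5' site that went to other junctions was 2.58%, 4.36% and 9.26% in the same order. Mean usage of the 55053 exon-skipping junctions was 1.74% ± 0.0123 (SD, n = 3), 5.57% ± 0.144 (SD, n = 3) and 14.3% ± 0.291 (SD, n = 3). These junctions were chosen by their mean over all 9 libraries, which lets in junctions near 0 in untreated cells that are high in treated ones, so the means describe the set. With the set defined in 1 untreated library, mean usage was 6.17% to 6.32% in the other untreated libraries, 14.7% to 15.0% with H3B-8800 and 19.2% to 19.4% with E7107, over the 3 choices of that library. The rise thus remained, while its size depended on the set. For each of the 3 measures, all libraries of one group lay above all libraries of the other in all 3 comparisons, with p = 0.1 in the exact permutation test, the smallest that 3 against 3 allows.

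**Figure D1:**
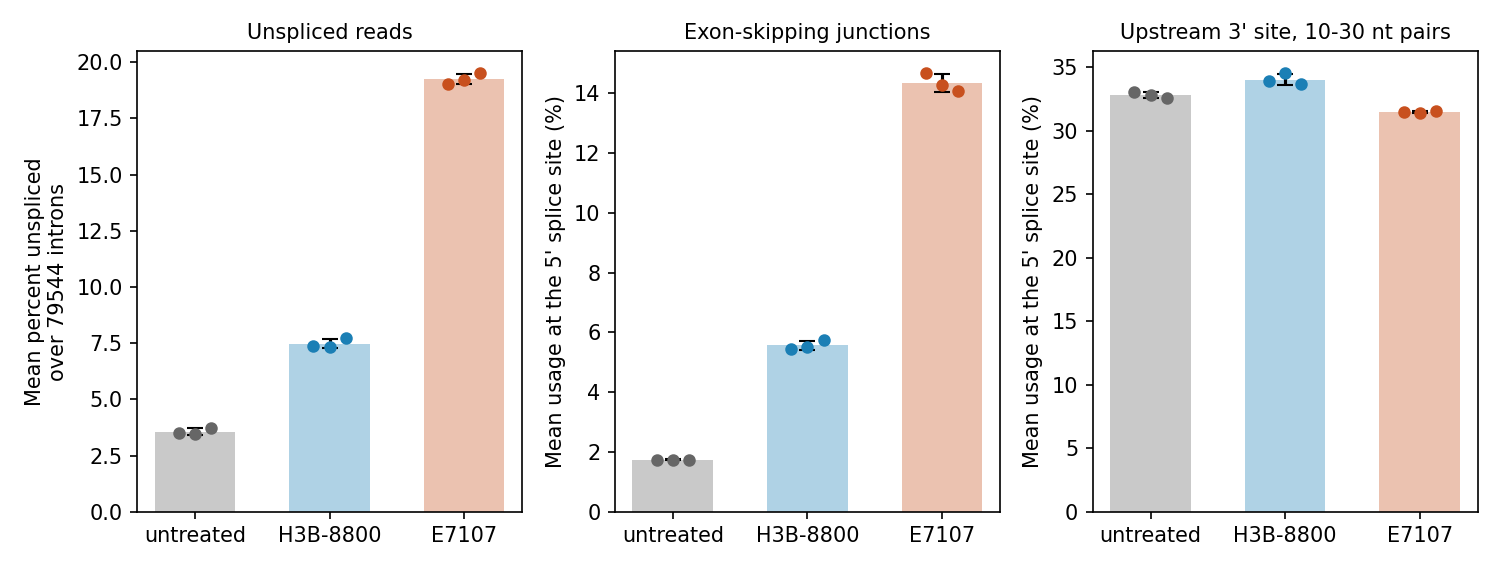
Mean percent unspliced over the tested introns, mean usage of exon-skipping junctions, and mean usage of the upstream member of pairs of 3' splice sites 10 to 30 nt apart, by group. Points are libraries, bars are means of 3 libraries and error bars are SD; unspliced reads went from 3.57% to 7.48% and 19.2%, and skipping from 1.74% to 5.57% and 14.3%, in junctions chosen by their mean over all 9 libraries.

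The comparison of H3B-8800 with untreated cells asks which introns and junctions respond to this compound in cells with mutant SF3B1. Retention rose in 7461 introns and fell in 59 of 79544. Introns with raised retention went on average from 8.87% ± 0.339 (SD, n = 3) unspliced to 31.7% ± 0.544 (SD, n = 3). They were short: their median length was 415 nt against 1428 nt in the other tested introns (permutation test, p = 1e-05, the smallest that the resamples can give). Retention rose in 21.7% of introns under 100 nt, in 9.93% of those from 500 to under 1000 nt and in 1.43% of those of 10000 nt and over.

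The share of introns called differed with the percent unspliced in untreated cells. With H3B-8800, retention rose in 1.65% of the 42948 introns under 1% unspliced in untreated cells, in 11.9% of the 24540 introns between 1% and 5%, in 32.7% of the 9375 introns between 5% and 20%, in 34.5% of the 1827 introns between 20% and 50% and in 14.5% of the 854 introns at 50% and over. Such a table follows in part from the minimum change of 10 percentage points, which is harder to reach from near 0 or near 100% on a fixed odds scale. Against resamples of introns matched on the untreated percent, a length difference remained. The median of raised introns minus that of the others was -1013 nt, and -345 nt in the matched resamples (permutation test, p = 1e-05). The test takes introns as replicates, so its p-value does not measure the spread between libraries. Of 9338 chains with at least 3 tested introns, 2815 held an intron with raised retention, 1343 of them held a single one, and in 33 chains every tested intron was called.

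The largest rise in retention with H3B-8800 was in an intron of 103 nt on the minus strand of chromosome 12, positions 56742844 to 56742946. It was 6.77% ± 2.72 (SD, n = 3) unspliced in untreated cells, 88.3% ± 4.69 (SD, n = 3) with H3B-8800 and 56.6% ± 11.7 (SD, n = 3) with E7107 (limma, adjusted p = 0.000133 for H3B-8800 against untreated). The largest fall was in an intron of 106 nt on the minus strand of chromosome 2, positions 179403567 to 179403672, from 72.4% ± 2.54 to 20.3% ± 6.43 (SD, n = 3; limma, adjusted p = 0.000307); with E7107 it was at 33.7% ± 5.16 (SD, n = 3).

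Junction usage with H3B-8800 changed at 9383 junctions, which lay at 5553 of the 52290 tested 5' sites. Usage rose at 4639 and fell at 4744 of them. Exon-skipping junctions made up most of the rises: 3593 of 55053 rose and 48 fell. From an untreated mean of 1.74%, few could fall by 10 percentage points. The 55053 were chosen by their mean over all 9 libraries, which lets in junctions because they are high in treated ones. The set defined in the untreated libraries held 17466, and calls were not counted in it. With no minimum change 7180 rose and 87 fell, and at an adjusted p under 0.01 2360 rose and 26 fell. Of 52290 main junctions, 715 were higher and 3832 lower. This is not a separate result: shares of a site sum to 100%, and from an untreated mean of 93.5% few main junctions could rise by 10 percentage points. The main junction was set over all 9 libraries, so it can be one at 0% in untreated cells, as at the chromosome 2 site below. The largest changes were at a single 5' site on the plus strand of chromosome 2. There the junction from 219447823 to 219449334 held 100% of spliced reads in every untreated library and 0% in every library of both treatments, and the junction from 219447823 to 219452308 held 0% and 100% (limma, adjusted p = 2.18e-06). With unspliced reads in the denominator, as deposited, 30.9% of the called junctions were higher, against 49.4% among spliced reads.

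Pairs of 3' splice sites 10 to 30 nt apart were examined because mutant SF3B1 is known to use cryptic 3' sites a short way upstream of the usual ones. No cells without the mutation were analysed here, so which of these sites depend on the mutation was not measured. Of 1122 upstream sites in near pairs, usage rose at 40 and fell at 25 with H3B-8800, and their mean usage was 32.8% ± 0.213 (SD, n = 3) untreated and 34.0% ± 0.430 (SD, n = 3) with H3B-8800. The 65 calls fell to 42 without untreated replicate 2, to 43 without untreated replicate 3 and to 41 without H3B-8800 replicate 3. At an adjusted p under 0.01 there were 28, 22 higher and 6 lower. Of 1353 upstream sites in far pairs, 119 rose and 24 fell, and mean usage was 34.9% and 39.5%. Near and far pairs were chosen by mean usage over all 9 libraries, which lets in sites near 0 in untreated cells that are high in treated ones. No pairs were defined in the untreated libraries alone, so the balance of rises and falls describes these sets.

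The comparison of E7107 with untreated cells asks the same of the second compound. Retention rose in 34193 introns and fell in 254, so that 43.0% of all tested introns were more retained. The raised introns went on average from 3.93% ± 0.156 (SD, n = 3) to 35.6% ± 0.274 (SD, n = 3) unspliced. Their median length was 910 nt against 1672 nt in the others (permutation test, p = 1e-05, the smallest that the resamples can give). Retention rose in 56.4% of introns under 100 nt, in 46.8% of those from 500 to under 1000 nt and in 21.3% of those of 10000 nt and over. Of the 9338 chains, 7074 held an intron with raised retention and in 991 every tested intron was called.

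**Figure D2:**
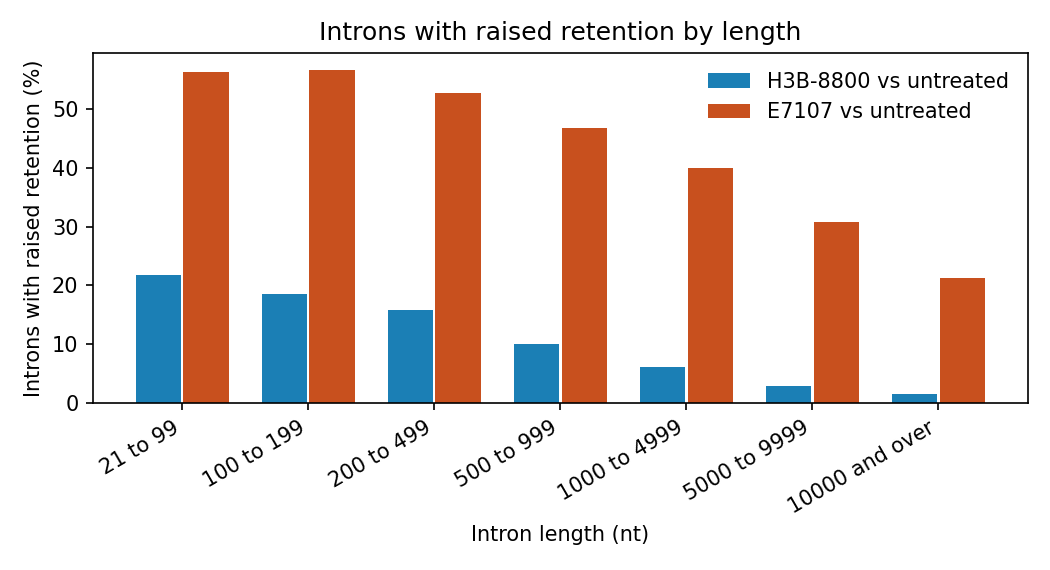
Percent of tested introns with raised retention (y axis) by intron length in nt (x axis), for each compound against untreated cells, 3 libraries per group. Introns under 100 nt were called in 21.7% (H3B-8800) and 56.4% (E7107) of cases, and introns of 10000 nt and over in 1.43% and 21.3%.

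The largest rise with E7107 was in an intron of 3300 nt on the minus strand of chromosome 10, positions 75436529 to 75439828, which was unspliced in 0% of reads in each untreated library and in 100% in each E7107 library (limma, adjusted p = 7.86e-05). With H3B-8800 it stood at 29.4% ± 27.7 (SD, n = 3), and the change from untreated was not called (limma, adjusted p = 0.0902). Read depth was unknown and no read minimum was applied, so these values may rest on few reads. The largest fall was in an intron of 265 nt on the plus strand of chromosome 4, positions 26859970 to 26860234, from 86.0% ± 3.94 to 24.4% ± 13.3 (SD, n = 3; limma, adjusted p = 9.96e-05). With H3B-8800 this intron was 83.2% ± 2.29 (SD, n = 3) unspliced.

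With E7107, usage changed at 34129 junctions at 17709 of the 5' sites, 16904 higher and 17225 lower. Exon-skipping junctions rose in 14811 cases, at 12947 different 5' sites, and fell in 236, while 1281 main junctions rose and 15196 fell. The choice of both sets over all 9 libraries limits these counts too. Among upstream sites of near pairs, 97 rose and 126 fell (69 and 68 at an adjusted p under 0.01), with a mean usage of 31.5% ± 0.0750 (SD, n = 3) against 32.8% untreated. In far pairs 242 rose and 99 fell. The pairs, too, were chosen over all 9 libraries. An exon-skipping junction on the minus strand of chromosome 1, positions 18062 to 24737, was 1 of 18 that went from 0% to 100% in every library, and was at 26.7% ± 3.24 (SD, n = 3) with H3B-8800 (limma, adjusted p = 3.11e-07 for E7107 against untreated). Of 26 junctions that went from 100% to 0%, 1 on the minus strand of chromosome 2, positions 160240192 to 160241665, held 100% of spliced reads in the untreated and H3B-8800 libraries and 0% in the E7107 libraries (limma, adjusted p = 3.11e-07). With unspliced reads in the denominator, 27.2% of called junctions were higher, against 49.5% among spliced reads.

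The direct comparison of H3B-8800 with E7107 asks how the effects of the 2 compounds differ at these doses. Retention was lower with H3B-8800 in 28601 introns and higher in 1895. The introns lower with H3B-8800 were 7.68% ± 0.249 (SD, n = 3) unspliced with it, 36.9% ± 0.266 (SD, n = 3) with E7107 and 3.33% in untreated cells. Over the 35949 introns called against untreated for either compound, the median difference in percent unspliced, H3B-8800 minus E7107, was -20.2 percentage points (SD 0.350 over the 9 pairs of libraries). The median size of the change from untreated was 2.91 percentage points with H3B-8800 and 25.0 with E7107. Most of these introns were called for E7107 alone; over the 6018 called for both, the sizes were 19.5 and 41.9 percentage points.

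The largest excess with H3B-8800 was in an intron of 232 nt on the minus strand of chromosome 12, positions 54107685 to 54107916. It was 28.7% ± 6.41 (SD, n = 3) unspliced in untreated cells, 71.7% ± 5.54 (SD, n = 3) with H3B-8800 and 0% in each E7107 library (limma, adjusted p = 4.03e-06 for the direct contrast). The largest excess with E7107 was in an intron of 180 nt on the minus strand of chromosome 16, positions 18473585 to 18473764, at 100% in each E7107 library, 0% in each H3B-8800 library and 4.17% ± 7.22 (SD, n = 3) untreated (limma, adjusted p = 1.31e-05). Values of exactly 0% and 100% may rest on few reads, since depth was unknown. Junction usage differed at 29992 junctions, 15212 higher with H3B-8800 and 14780 lower. Exon-skipping junctions, chosen over all 9 libraries, were lower with H3B-8800 in 12051 cases and higher in 1740. Upstream sites of near pairs, chosen likewise, were higher in 131 and lower in 60 (83 and 37 at an adjusted p under 0.01). With unspliced reads in the denominator, 71.8% of called junctions were higher with H3B-8800, against 50.7% among spliced reads. The junction on chromosome 2 from 160240192 to 160241665 was 1 of 6 at 100% with H3B-8800 and 0% with E7107 (adjusted p = 3.96e-07). A skipping junction on the minus strand of chromosome 1, positions 26310579 to 26317217, was 1 of 6 with the opposite difference, at 100% with E7107 alone and at 0% in the 6 other libraries (limma, adjusted p = 3.67e-07).

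**Figure D3:**
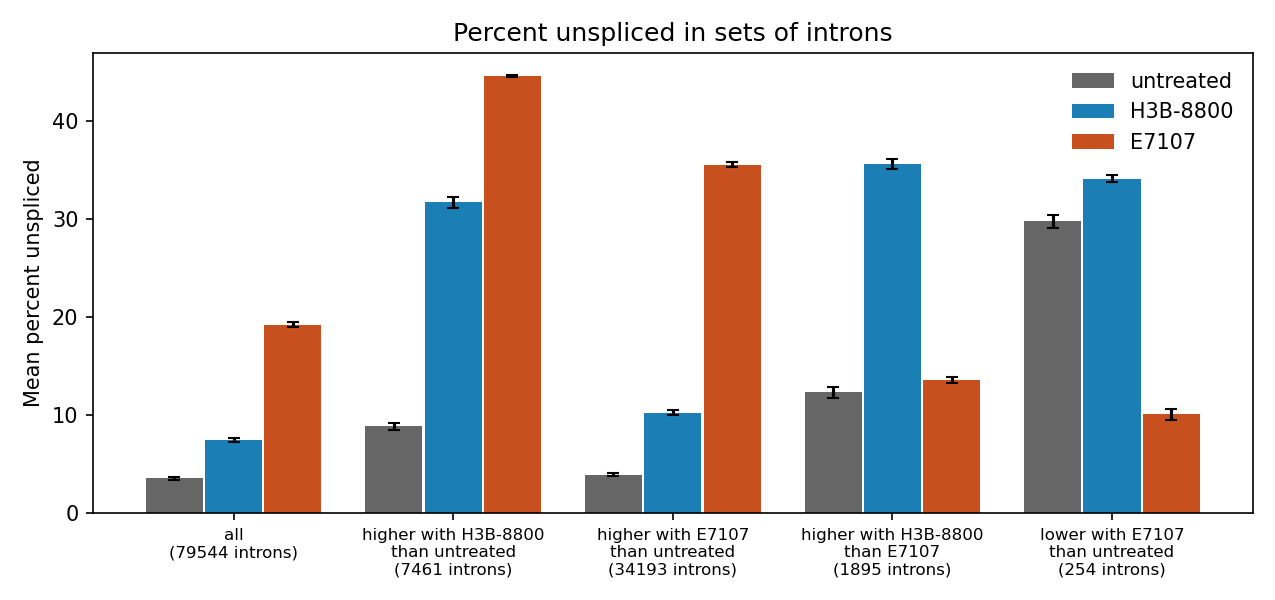
Mean percent unspliced (y axis) in all tested introns and in sets of called introns, by group. Bars are means of 3 libraries and error bars are SD over libraries. The 1895 introns higher with H3B-8800 than with E7107 were at 12.3%, 35.6% and 13.6% in untreated, H3B-8800 and E7107 cells; the sets were chosen by these values, so the bars describe them and test nothing.

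The calls of the 2 compounds overlapped. Of the 7461 introns raised by H3B-8800, 5957 were also raised by E7107, where independent lists would share 3207. That number takes all introns as equally likely to be called. In introns under 1% unspliced in untreated cells, 1.65% rose with H3B-8800 and 32.4% with E7107. Between 5% and 20%, 32.7% and 61.8% rose. Part of the excess over 3207 may come from this. Simulated unchanged groups against the same 3 untreated libraries shared 0 in each of 50 draws. Unchanged groups give almost no calls, so this 0 does not show how much overlap the shared controls create among real calls. For junctions, 2727 rose with both compounds and 3330 fell with both, against 578 and 602 for independent lists. Across introns the changes in log2 odds had a correlation of 0.342 (simulated 0.113) and a covariance of 0.694 (simulated 0.0167); across junctions they were 0.510 (simulated 0.245) and 2.45 (simulated 0.109). Part of the excess in shared calls may come from the shared controls, since 3 libraries cannot be split with at least 2 in each part. The simulated groups were drawn around the mean of the same untreated libraries, so error in that mean, which both comparisons share, was left out. The simulated correlations and covariances thus cannot show how much the shared controls gave.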

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

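The tests of held-out libraries, of denominators and of linked introns were written down before their values were seen; the patterns they address, and the counts of splits, were chosen after the results were seen.

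A difference between the compounds singled out 1895 introns that were more unspliced with H3B-8800 than with E7107 in the direct contrast, against the general trend. Their means were 12.3% ± 0.528 in untreated cells, 35.6% ± 0.478 with H3B-8800 and 13.6% ± 0.287 with E7107 (SD, n = 3), and 80.3% of them were 2% to 40% unspliced in untreated cells, against 29.4% of all tested introns. That share was not particular to them: it was 76.4% in introns raised by H3B-8800, 79.1% in those lowered by E7107 and 76.3% in those lowered by H3B-8800. Noise in thinly covered introns would not carry over to other libraries, but the 1711 introns called without replicate 3 of both compounds differed by 17.3 percentage points in the libraries left out, and 87.4% of them were higher with H3B-8800 there. Reads drawn to other junctions by E7107 could lower its percentages, but with those reads left out the difference was 23.6 percentage points (22.7 to 24.3 over the pairs of libraries), against 22.0 with them. The cause stays open; loss of unspliced RNA from such genes with E7107 could not be examined because expression was not analysed here.

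A subset of 26 introns rose with H3B-8800 and fell with E7107, each against untreated cells. Chosen by these values, they were 28.3% ± 1.36, 56.1% ± 2.54 and 9.65% ± 0.850 unspliced in untreated, H3B-8800 and E7107 cells (SD, n = 3).

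Short introns rose more with H3B-8800. Wholly unspliced RNA or genomic DNA carried evenly into the treated libraries would raise all introns of a transcript about alike. The shortest intron of a chain rose by 1.50 percentage points more than the longest (standard error 0.0931 over 9338 chains, 4.38 against 2.88). Differences between whole transcripts, such as their mean coverage, would likewise not act within a chain. There the shortest intron rose more in 56.5% of the chains whose 2 introns differed, and in 55.1% to 55.7% of all chains in each H3B-8800 library. These values argue against both, so defined, as the whole cause. Partly spliced RNA, coverage along a transcript and the untreated percent (6.43% under 100 nt, 2.36% at 10000 nt and over) were not matched within chains and stay open. The difference within chains was smaller than that between bins of length, so a part from differences between transcripts stays open. The pattern was not particular to this compound: with E7107, 56.4% of introns under 100 nt rose, and 21.3% of those of 10000 nt and over. Its cause stays open.

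Outside the main measurement, more of the 1352 mitochondrial junction rows were above 0 with E7107. Read depth was unknown, and whether these numbers follow it was not tested. A mean of 237 such rows was above 0 with E7107 (218 to 252), against 177 in untreated cells (152 to 190) and 139 with H3B-8800 (118 to 168).

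For all 6 counts of called features, the 10 splits of 6 libraries into 3 and 3 were too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls. For introns the real counts were 7520 (H3B-8800), 34447 (E7107) and 30496 (H3B-8800 against E7107), and the highest other splits gave 6, 0 and 0. For junctions they were 9383, 34129 and 29992, and the highest others gave 24, 1 and 2.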

How the results depend on the processing

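Counts moved by over 1.5 times under few settings, and no named feature or per-library difference changed sign. Which direction held more of the called junctions turned under 5 (H3B-8800), 6 (E7107) and 6 (H3B-8800 against E7107) of 19 settings. These were no minimum change and an adjusted p under 0.01 in each comparison, the replicate block and leaving out H3B-8800 replicate 1 or 2 with H3B-8800, and a pseudocount of 0.1 and leaving out any E7107 library in the others. With no minimum change, 8952 rose and 7992 fell with H3B-8800, 26187 and 23995 with E7107, and 21721 were higher and 22938 lower with H3B-8800 than with E7107. Tests with an adjusted p under 0.01 (planned for the overlap), the deposited denominator, other pseudocounts, no trend, a mean of 5% to 95% and the matched length background, and exon-skipping sets defined in untreated libraries, were chosen after the data were seen. With no minimum change, introns called were 17287, 54802 and 48662 (H3B-8800, E7107, and H3B-8800 against E7107), and junctions with H3B-8800 16944. With the lower of the 2 boundaries, introns called were 4572, 22827 and 20327; the cause was not tested. With the deposited denominator, junctions called were 15039, 52636 and 45780, of 144842 tested against 135717. Retention then lowers all junctions of a site, and the tested set also changed. The 2 were not told apart. At an adjusted p under 0.01, junctions with H3B-8800 were 5723 and junctions lower with both compounds 2080. With exon-skipping junctions defined in all 3 untreated libraries, differences in mean usage were 8.12, 12.6 and -4.47 percentage points. Over introns called for both compounds, the median difference was -18.2 percentage points. The other counts of called introns and junctions stayed within 1.5 times; of 102 recounts of exon-skipping junctions and near pairs, 10 did not, 7 of them with no minimum change or an adjusted p under 0.01 and 3 without 1 library, as given with those pairs. Besides, without each library in turn, introns with H3B-8800 were 6486 to 7777 and junctions 7420 to 10043. The named features were called under all settings run for them.

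No pairing by replicate number was seen. For same-numbered libraries, deviations from the group means correlated between -0.0118 and 0.0105 over introns and between -0.00964 and 0.00254 over junctions. Noise at unknown depth could hide a pairing, so these values do not exclude one. With the replicate block, introns called were 7190, 34422 and 30254, and junctions with H3B-8800 7740.

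Not run, for want of counts, gene names or sequence, were the alternatives for gene expression and gene lists, the read minimums, 0.5 reads as a pseudocount, the matching of length on reads, and GC content. Unknown depth limits all percentages, including those of 0% and 100%. The column headers number the H3B-8800 libraries apart from the others (532 to 534 against 550 to 555); if this marks a batch, it cannot be told apart from the treatment.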

Other observations

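The comparison of boundaries, the means of introns that fell and the number able to fall were computed after the results were seen; the counts of falls and of shared falls had been planned. Percent unspliced differed between the 2 boundaries of introns. Each boundary's percent is a share of all reads at its own site, those of other junctions included. How far the differences come from these denominators was not tested. In untreated cells, mean percent unspliced was 3.29% at 5' boundaries and 3.85% at 3' boundaries, and with H3B-8800 it was 7.03% and 7.92%. With E7107 the order was turned, at 19.5% and 19.0%. The difference between the 5' and the 3' boundary was -0.566 percentage points in untreated cells, -0.889 with H3B-8800 and 0.419 with E7107, with no overlap between libraries of different groups (exact permutation test, p = 0.1 in each comparison, the smallest possible with n = 3).

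A fall of 10 percentage points was possible only in the 6113 introns with at least 10% unspliced in untreated cells, so called falls start high by rule. The 254 introns lower with E7107 were 29.8% ± 0.667 unspliced in untreated cells, 34.2% ± 0.359 with H3B-8800 and 10.1% ± 0.528 with E7107 (SD, n = 3). The 59 introns lower with H3B-8800 were at 33.3% ± 1.17, 15.5% ± 0.218 and 32.1% ± 1.55, and 22 of them were also lower with E7107 while 13 were higher. Among the 6113 introns, independent lists would share 2.45; part of the excess may come from the shared controls.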
